A study of Mus musculus with 7 samples.

How the data were processed

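Chromatin immunoprecipitation for H3K27me3 was followed by sequencing in sorted epidermal progenitor cells of newborn mice. Groups were taken from the sample titles and, for the 2KO and input libraries, from the genotype label. Control and Ring1a/b double-knockout (2KO) cells had 2 labelled immunoprecipitation libraries each. The 1 control input library and the libraries of cells with conditional loss of Eed (1 input, 1 H3K27me3) had no peak list and were not analysed here. The 2KO titles name H3K27me1, whereas the antibody field and the deposited list name H3K27me3.

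Reads were aligned with Bowtie2 2.3.3.1 and handled with SAMtools 1.9 on mouse build mm10, per the submitters' processing notes. The authors deposited 1 list of called peaks per genotype, with chromosome, start and end position and no height, fold, score or p-value. The peak caller, its threshold, the use of the input libraries and whether the replicates were pooled are not given in the sources used here. A stricter threshold or shallower sequencing in either list would change its number of peaks, and a position without a called peak is not a position without the mark. Starts were read as 0-based and are printed 1-based. Depth per library is not held in the lists, so no floor of detection can be given.

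Peaks overlapped when they shared at least 1 bp. The number, covered length and width of peaks, overlaps in both directions, the Jaccard index of covered bases and the log2 ratio of covered bases in merged shared regions were computed in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3; shares have 95% Wilson intervals. Overlaps were set beside 1000 placements of the other list at random on the same chromosomes with widths kept. Placement at random gene ends was added after the data were seen.

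Genes came from a RefSeq table of assembly GRCm38.p6, which is the same build as mm10. It gives the start and end of a gene and no strand, exon or UTR, so transcription start sites could not be placed as planned. A gene was called marked when a peak overlapped either gene end extended by 1 kb, over 21631 protein-coding genes of the autosomes and the X chromosome. No genome sequence was used, so the planned GC and CpG content was not computed. Peaks were ranked by width where a rank was needed, since the lists hold no score.

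The 16 gene lists, with 474 symbols of which 2 were missing from the table, and the rules for named genes were fixed before the data were examined. Named were up to 4 genes per list and class (both lists, control only, 2KO only) at the widest peaks, the 10 genes at the widest peaks of each class, and Ring1, Rnf2 and Eed. Genes named outside this rule are marked as such. For each list, the share of control-marked genes also marked in the 2KO list was placed among 10000 draws of as many control-marked genes from the same of 5 equal classes of control peak width. This percentile describes these lists and is no p-value, since genes share peaks and are not replicates.

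The overlap code was tested on a simulated 2KO list made from the 3631 control peaks: all 2144 peaks kept by construction and all 150 added ones were found, with 0 wrong. Of 100 random gene lists, 5 fell outside the central 95% of their draws. Alternatives covered the overlap required, the distance allowed, a stricter cut-off by width, equal numbers of peaks, merging of close peaks, the chromosomes used, and the window and target at genes. Alternatives added after the data were seen were the retained bases per list with different matchings, the 3 transcription factor lists other than Hox pooled, the class of a gene by whether its peak had any counterpart, and draws from the 100 genes nearest in peak width. Figures were drawn with matplotlib 3.10.9.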

Results

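Trimethylation of lysine 27 on histone H3 (H3K27me3), the repressive mark laid down by Polycomb repressive complex 2, was mapped by chromatin immunoprecipitation and sequencing in epidermal progenitor cells of newborn mice (postnatal day 0). Cells were sorted by flow cytometry. Control cells were set beside cells lacking both Ring1a and Ring1b (the double knockout, 2KO), the catalytic ubiquitin ligases of Polycomb repressive complex 1, encoded by Ring1 and Rnf2. Each of these genotypes had 2 labelled immunoprecipitation libraries and 1 list of called peaks. The sample titles of the 2KO libraries name monomethylation, H3K27me1, whereas their antibody field and the peak list name H3K27me3; the list was read as H3K27me3. The 1 input library of control cells, and the 1 input and 1 H3K27me3 library of cells with conditional loss of Eed, a core subunit of Polycomb repressive complex 2, were not analysed here. The control list held 3631 peaks covering 24.8 Mb, with a median width of 4764 bp (quartiles 3043.5 and 7487.5 bp). The 2KO list held 2340 peaks covering 16.4 Mb, with a median width of 5507 bp (quartiles 3740.5 and 8203.5 bp). With 1 list per genotype there was no replicate error and no test between genotypes, and sequencing depth was unknown. Intervals are 95% Wilson intervals and cover counting error only.

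To examine which H3K27me3 regions of control cells were still called without Ring1a and Ring1b, the control list was compared with the 2KO list. Domains over the cell-cycle inhibitor genes Cdkn2a and Cdkn2b (chromosome 4, 89266471 to 89313116, 46.6 kb) and over Lhx2, which encodes a LIM homeodomain factor of hair follicle progenitors (chromosome 2, 38330926 to 38374838, 43.9 kb), had no 2KO peak. The 4 Hox clusters kept little of their called length. The domain over Shh, which encodes a morphogen of hair follicle development (chromosome 5, 28455297 to 28469412, 14.1 kb), was called at almost the same place in the 2KO list (28455270 to 28469233, 14.0 kb). Over the whole genome, 1721 of 3631 control peaks overlapped a 2KO peak (47.4%, 45.8 to 49.0) and 1910 did not. Random placement of the 2KO peaks gave a mean of 1.36% (0.854 to 2.12 over 1000 placements), and placement at random gene ends gave 4.66% (3.58 to 5.76). The ratio of 2KO to control was 0.644 for the number of peaks and 0.659 for the covered length, and the lists shared 11.8 Mb, which is 47.5% of control bases and 72.1% of 2KO bases (Jaccard index 0.401, against a mean of 0.00421 under random placement).

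Control peaks with a 2KO counterpart were wider (median 5823 bp) than those without one (3960.5 bp) and lay within 1 kb of an end of a protein-coding gene more often (66.0% against 45.8%). Of the control peaks at gene ends, 1135 of 2010 had a 2KO peak (56.5%, 54.3 to 58.6), compared with 586 of 1621 away from gene ends (36.2%, 33.8 to 38.5). Over 5 equal classes of control peak width, from narrowest to widest, the share with a 2KO peak went from 27.1% to 67.8%. A wide peak meets an overlap of 1 bp more easily. By bases under 2KO peaks the rise was smaller, from 27.2% to 52.8%. In the widest class the share with a 2KO peak was 80.3% (76.6 to 83.6, n = 498) at gene ends and 40.4% (34.2 to 46.8, n = 228) elsewhere. This class spans 8614 to 131323 bp, and widths inside it were not matched.

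**Figure D1:**
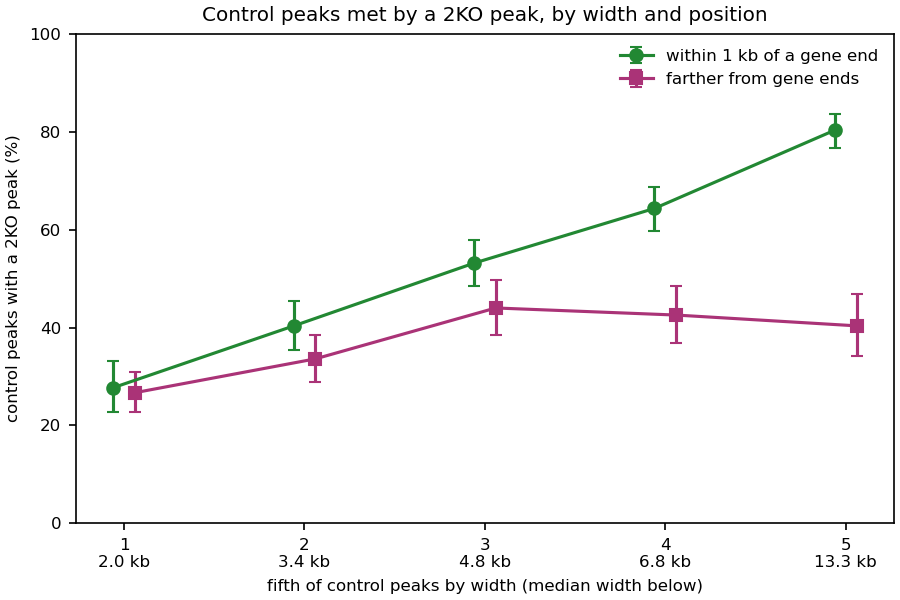
Percent of control H3K27me3 peaks that overlap a 2KO peak (vertical axis) in 5 classes of control peak width (horizontal axis, median width in kb below each class), for peaks within 1 kb of a gene end (circles) and for the others (squares); bars are 95% Wilson intervals. The shares at gene ends go from 27.7% to 80.3%, and those elsewhere stay at or below 44.0%.

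The Hox genes, which encode the homeodomain factors of body axis patterning, showed the lowest retention of the transcription factor lists. In the HoxA cluster (chromosome 6, 52155367 to 52260880), 48.6 kb lay under control peaks and 0 kb under 2KO peaks. The called length went from 74.9 to 9.86 kb in HoxB (chromosome 11, 96194316 to 96368254), from 69.6 to 6.81 kb in HoxC (chromosome 15, 102921131 to 103036856) and from 96.9 to 24.5 kb in HoxD (chromosome 2, 74668225 to 74765142). The widest control peak of the genome, 131.3 kb over HoxD and Evx2 (74639113 to 74770435), was met by several separate 2KO peaks that together covered 39.99% of it. Hoxd13, Hoxd12, Hoxd11 and Hoxd1 were marked in both lists, whereas Hoxd10, Hoxd9, Hoxd8 and Hoxd4 were marked in the control list only. This split depends on the window at gene ends. The 2KO peak that marked Hoxd11 (74686900 to 74693821) lay inside Hoxd10, short of the windows at its ends. Hoxd13 was marked by a 2KO peak that ended outside the gene. The 105.3 kb control peak from Hoxa9 to Evx1 was covered to 30.8%, and 16.8 kb of that was a 2KO peak next to Hoxa13, outside the cluster proper. The 97.0 kb control peak over Hoxc13 to Hoxc9 was covered to 7.02%. In HoxB, a 48.7 kb control peak that reaches from outside the cluster over Hoxb13 (96161191 to 96209908) was covered to 63.9%, mostly outside the cluster, and the 39.3 kb peak at Hoxb9 and Hoxb8 (96245587 to 96284846) to 17.3%. Hoxa9, Hoxb8, Hoxb9, Hoxb13, Hoxc9 and Hoxc13 are named only to place these peaks, after their values were seen. Of 39 Hox genes, 26 were marked in control cells and 10 of these in both lists (38.5%, 22.4 to 57.5). This lay at percentile 0.01 of 10000 draws of control-marked genes from the same classes of peak width (central range 57.7 to 88.5%). With peaks required at the gene ends themselves the share was 16.7%. These 26 genes lay on 8 control peaks, so the draws of single genes overstate how far the clusters stand apart. The bases of these peaks were also counted, a unit chosen after the data were seen. By bases the percentile was 9.88 with draws from all control peaks of the same width class (central range 18.7 to 81.3%). It was 1.21 with draws from gene-end peaks nearest in width. The Hox peaks of 131.3, 105.3 and 97.0 kb were the widest of the control list, and the next measured 76.4 kb. No draw of other peaks could match them in width, so these percentiles cannot separate Hox membership from great width.

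**Figure D2:**
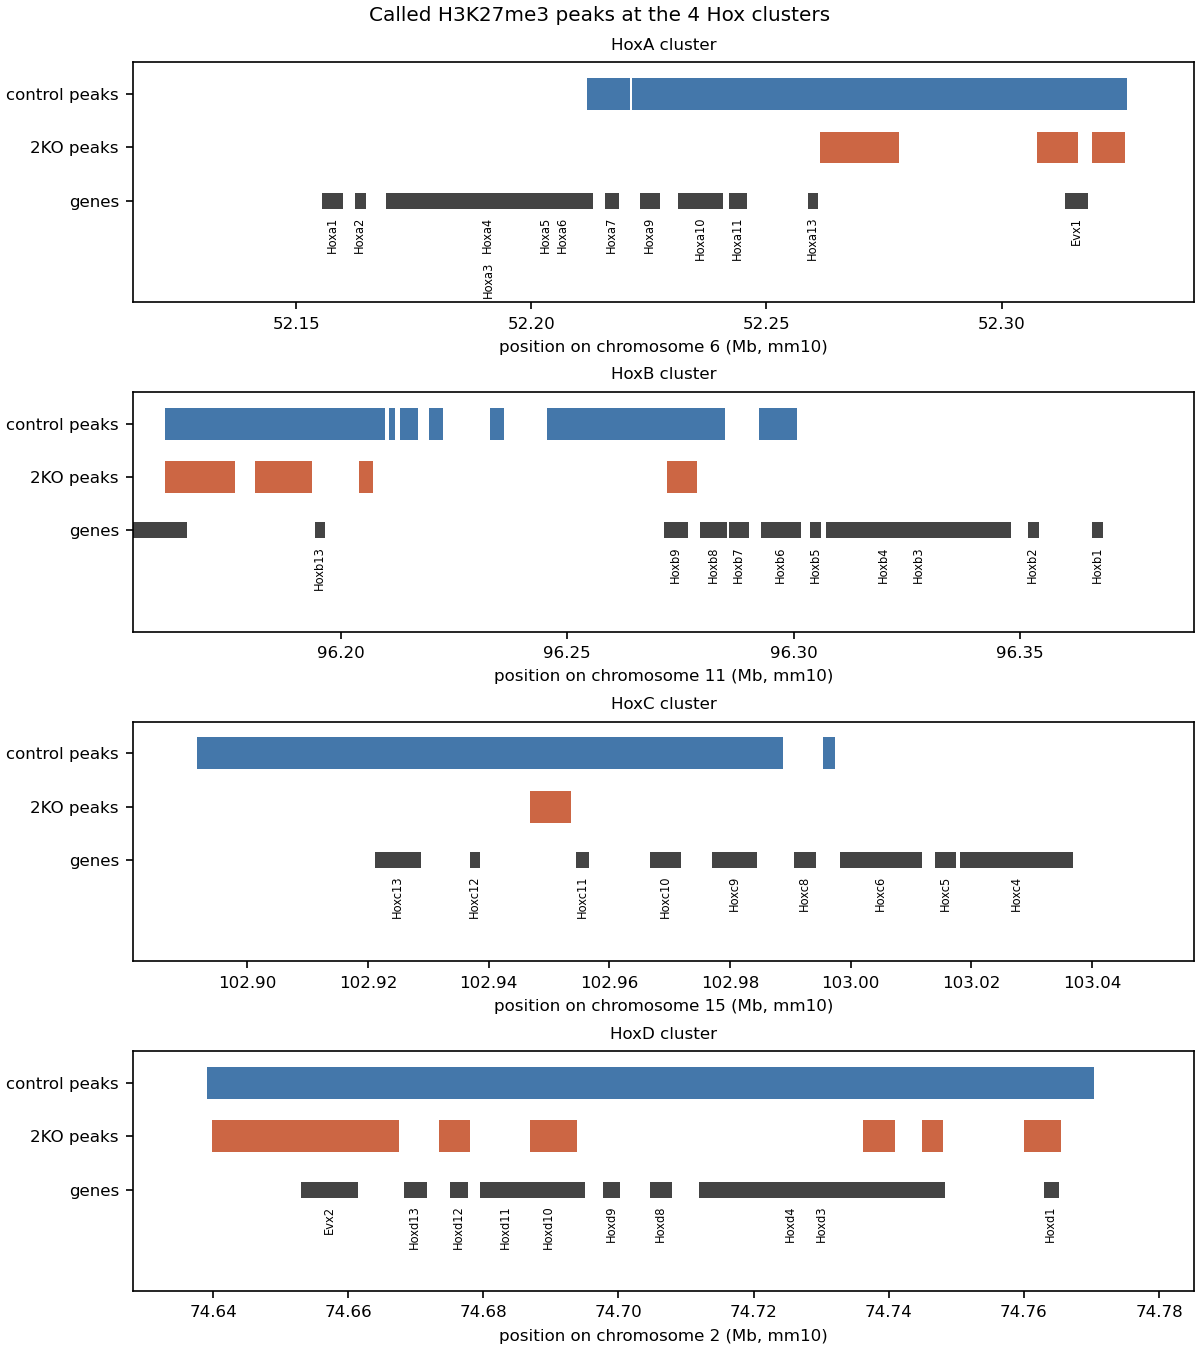
Called H3K27me3 peaks of control (upper bars) and 2KO cells (middle bars) and annotated genes (lower bars) at the 4 Hox clusters, with position in Mb of mm10 on the horizontal axis; bars stand for called intervals, not signal height, and only Hox and Evx genes are named. HoxD is covered throughout in the control list and to 25.3% in the 2KO list.

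Other developmental transcription factor genes, which are classical Polycomb targets, were mostly marked in both lists. Of 58 neurogenic and myogenic basic helix-loop-helix and neuronal factors, 52 were marked in control cells and 47 of these in both lists (90.4%, 79.4 to 95.8, percentile 99.97 of the matched draws). Counted by retained bases, the percentile of this list was 99.7 with draws from all control peaks of the same width class and 84.3 with draws from gene-end peaks nearest in width, so it depended on the matching. Among these genes, Hand2, a factor of heart and limb development, had a 56.9 kb control and a 49.6 kb 2KO peak, and Zic4 had peaks of 76.4 and 34.7 kb. The Zic4 control peak was covered to 64.8% by several 2KO peaks. Evx1 and Evx2 also counted as marked in both lists. They lay on the HoxA and HoxD control peaks, covered to 30.8 and 39.99%, so these peaks enter the Hox list too. Emx2 and Vax1, forebrain homeobox genes with control peaks of 27.8 and 21.0 kb, and Phox2a (6.67 kb) had no overlapping 2KO peak. Neurod6 was marked in the 2KO list only, by a peak of 4.82 kb. In the list of Pax, Lhx, Dlx, Irx, Nkx and related homeobox genes, 33 of 46 control-marked genes were marked in both lists (71.7%, 57.5 to 82.7, percentile 50.3), among them Pax2 with peaks of 54.0 and 40.1 kb and Pax3 with 57.8 and 24.6 kb. Their control peaks were covered to 81.0 and 42.6%. Nkx2-3, Dlx5 and Nkx2-2 were marked at their ends in the control list only, although 2KO peaks covered 68.7, 66.2 and 61.2% of their control domains. In the Tbx, Gata, Fox and Sox list, 37 of 48 were marked in both (77.1%, 63.5 to 86.7, percentile 76.8). Foxa2, a factor of endoderm and floor plate, had a 39.5 kb control peak covered to 96.5%, whereas the 26.6 kb domain of Foxb1 had no 2KO peak and those of Gata4 and Tbx3 were covered to 52.7 and 30.7%.

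Genes of the skin lineages fell into different classes. None of the 22 basal progenitor genes and none of the 20 housekeeping genes annotated was marked in either list. Of 33 epidermal differentiation genes, Tchh (3.44 kb) and Prdm1 (5.90 kb) were marked, both in the control list only. Of 21 genes of Merkel cells, the mechanosensory cells of the epidermis, 13 were marked in control cells and 10 of these in both lists (76.9%, 49.7 to 91.8, percentile 78.6). Gfi1, a Merkel cell transcription factor, had peaks of 27.3 and 28.4 kb and Isl1 of 30.6 and 19.9 kb, with 92.1% of the Isl1 control peak under 2KO peaks. Atoh1, the bHLH factor that specifies Merkel cells, had peaks of 10.9 and 8.92 kb and was named after its values were seen. Sox2, with a 36.6 kb control domain covered to 26.9%, Krt18 and Nrcam were marked in the control list only. Krt8 and Krt18 encode keratins of simple epithelia and Merkel cells. Their 49.4 kb domain (chromosome 15, 101997134 to 102046499) was covered to 4.82%, by a 2.38 kb peak at Krt8, so Krt8 counted as marked in both lists. By bases, a unit chosen after the data were seen, the 12 control peaks of the Merkel list kept 57.6%. This lay at percentile 66.0 of draws from the same width class and 35.2 of gene-end peaks nearest in width. Of 33 hair follicle genes, 12 were marked in control cells and 5 of these in both lists (41.7%, 19.3 to 68.0, percentile 5.62). Shh, Msx1, Fgf5 and Lgr5 were among these 5. By contrast, Lhx2, Cux1 (24.0 kb), Tbx1 (14.5 kb) and Nfatc1 (10.9 kb) had control peaks with no 2KO counterpart. The Cux1 peak lay within 1 kb of the gene but wholly outside it. With a window of 0, 9 hair follicle genes were marked in control cells and 4 of these in both lists.

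**Figure D3:**
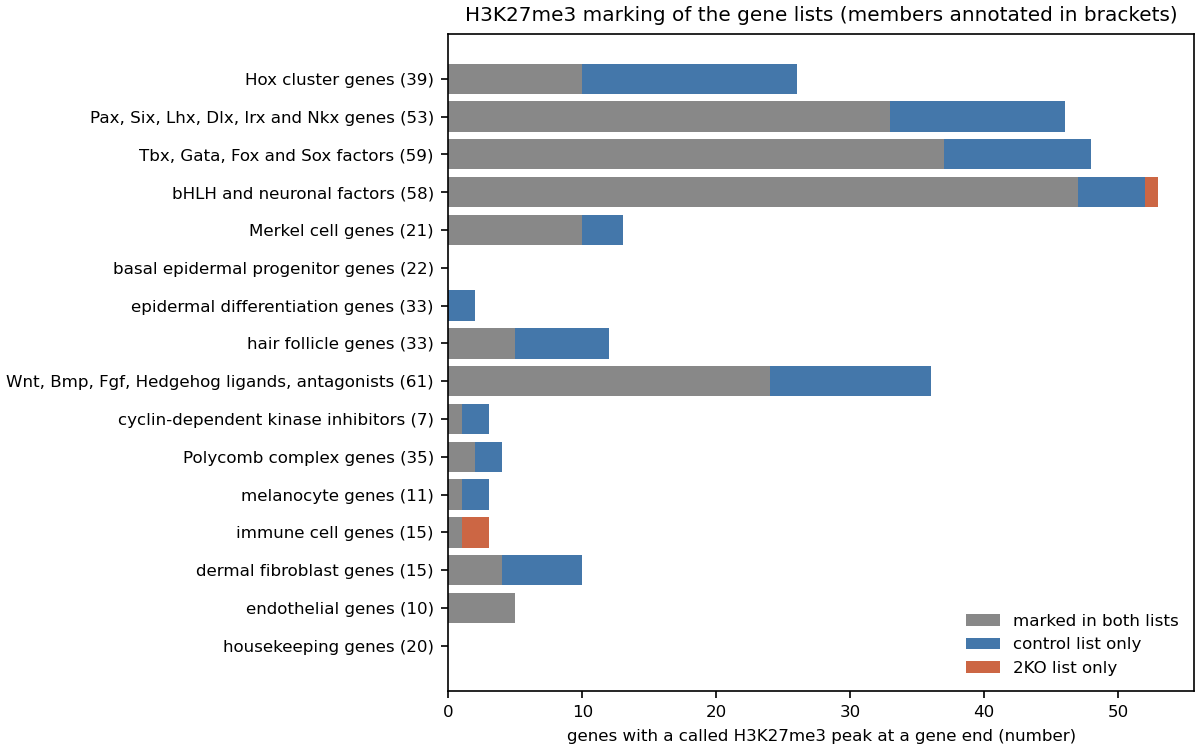
Number of genes of each list (horizontal axis) with a called H3K27me3 peak within 1 kb of a gene end, split into genes marked in both lists, in the control list only and in the 2KO list only; the number of annotated members stands in brackets. Of 52 control-marked bHLH and neuronal factors 47 are marked in both lists, against 10 of 26 Hox genes. The 47 include Evx1 and Evx2, which lie on control peaks of HoxA and HoxD.

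Signalling genes lay between these. Of 36 control-marked ligands and antagonists of the Wnt, Bmp, Fgf and Hedgehog pathways, 24 were marked in both lists (66.7%, 50.3 to 79.8, percentile 74.9). The peak of Wnt1 measured 22.1 kb in each list, and that of Ihh 16.9 and 18.6 kb. Wnt5a (15.2 kb), Inhbb (9.46 kb), Gdf10 (9.40 kb) and Fgf10 (9.18 kb) were marked in the control list only. Among 3 marked cyclin-dependent kinase inhibitors, Cdkn2c had peaks of 6.53 and 5.75 kb within 1 kb of the gene but wholly outside it. Cdkn2a and Cdkn2b, which lay under a control domain, had no 2KO peak. With a window of 0, 2 of the inhibitor genes were marked in control cells and 0 of these in both lists. Among Polycomb genes, Pcgf1 and Cbx8 were marked in both lists and Bmi1 and Epop in the control list only. The peaks of Pcgf1 (15.4 and 17.7 kb) and Bmi1 (6.54 kb) lay within 1 kb of the gene but wholly outside it. The widest peaks at Cbx8, 14.9 kb in control and 4.27 kb in 2KO cells, did not overlap each other. 2KO peaks covered 48.5% of the former, and control peaks 91.8% of the latter. With a window of 0, 2 Polycomb genes were marked in control cells and 1 of these in both lists. Neither Ring1, Rnf2 nor Eed was marked in either list, so the lists do not check the genotype.

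**Figure D4:**
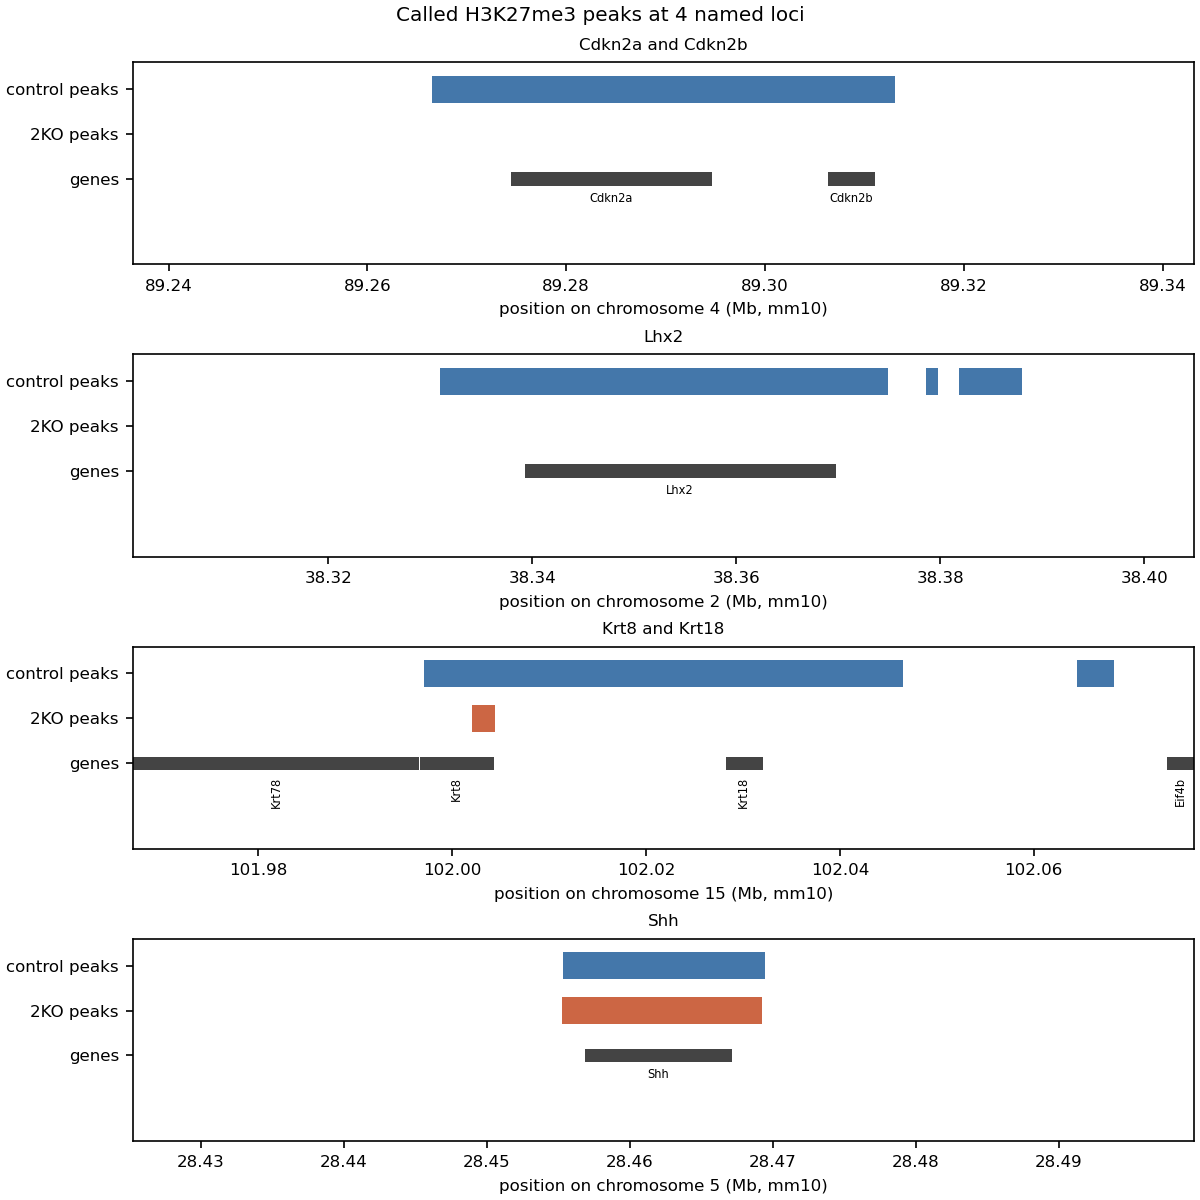
Called H3K27me3 peaks of control (upper bars) and 2KO cells (middle bars) and annotated genes (lower bars) at 4 loci, with position in Mb of mm10 on the horizontal axis. Cdkn2a with Cdkn2b and Lhx2 have no 2KO peak, Krt8 with Krt18 have a 2.38 kb one, and Shh has one of 14.0 kb beside a control peak of 14.1 kb.

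Lists of other cell types that a sort could hold were small and marked to differing extents. In control cells 10 of 15 dermal fibroblast, 5 of 10 endothelial, 3 of 11 melanocyte and 1 of 15 immune genes were marked. Of 10 control-marked dermal fibroblast genes, 4 were marked in both lists (40%, 16.8 to 68.7, percentile 8.42): Twist1, Twist2, Pdgfra and En1. Prrx1, Crabp1, Fbn1 and Vim were among those of the control list only. The endothelial factor Sox17 had a peak of 22.1 kb in control and 22.2 kb in 2KO cells, and all 5 control-marked endothelial genes were marked in both lists (56.6 to 100.0%, percentile 92.6). Of 3 marked melanocyte genes, Sox10 was marked in both lists and Kit and Ednrb in the control list only. Of the immune genes, Ikzf1 was marked in both lists, and Cd207 and Cd3g in the 2KO list only. Their 2KO peaks overlapped control peaks over 59.6 and 54.7% of their length. That of Cd207 (chromosome 6, 83677647 to 83710602) met only an end of the gene (83671207 to 83677857). Counted over all 21631 protein-coding genes, 2180 were marked in control cells, 1435 in 2KO cells and 1210 in both (55.5% of the control-marked, 53.4 to 57.6). Of the 970 genes marked in the control list only, 889 lay at peaks with no 2KO counterpart and 81 at a shared peak. The count of 970 became 597 when equal numbers of the widest peaks were compared.

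To examine whether the 2KO list held regions absent from the control list, the comparison was made in the other direction. Most 2KO peaks, 1792 of 2340 (76.6%, 74.8 to 78.3), overlapped a control peak, compared with means of 2.12% for random placement and 7.72% for placement at gene ends. The remaining 548 were narrow (median 3783 bp), covered 2.16 Mb and lay at gene ends in 29.0% (25.4 to 33.0), with 48.2% between genes. The widest of them at gene ends lay within 1 kb of Zbtb40, a zinc finger gene (chromosome 4, 137049285 to 137061055, 11.8 kb), followed by Actl6b, which encodes a neuronal chromatin remodelling subunit (chromosome 5, 137551626 to 137561141, 9.52 kb), and Nr0b2, an orphan nuclear receptor gene (chromosome 4, 133549106 to 133558532, 9.43 kb), all named after their values were seen. Of 225 genes marked in the 2KO list only, 170 lay at peaks with no control counterpart and 55 at a shared peak that reached the gene end in the 2KO list alone. The 10 genes of this class at the widest 2KO peaks, such as Atp8b3 (41.6 kb, 76.4% of it under control peaks) and Myt1l (14.1 kb, 37.9%), were of the second kind. The count of 225 became 391 with a window of 5 kb at gene ends and 419 with equal numbers of the widest peaks.

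To examine whether shared regions changed in width, called bases were compared in the 1676 merged regions that held peaks of both lists. At Gfi1, Sox17 and Wnt1 the called width differed by little, and at Hand2, Pax2 and the HoxD domain it was smaller in the 2KO list. The median log2 ratio of 2KO to control was 0.10 (quartiles -0.28 and 0.47), with 987 regions wider and 689 narrower in 2KO cells. Regions with a geometric mean width under 10 kb were wider at the median, by 1.18-fold between 3 and 5 kb (472 regions). Those from 10 to 20 kb had a ratio of 0.965 (248 regions) and those of 20 kb or more 0.941 (126 regions, 81 of them narrower). Peaks of 20 kb or more numbered 190 in the control and 90 in the 2KO list. The median log2 ratio was 0.012 when equal numbers of the widest peaks were compared.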

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

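No paired analysis was possible because each genotype had 1 peak list, although the labels share replicate numbers; for the same reason no replicate could be left out. The planned use of the 5'-most start site was not run, since the gene table has no strand, and the gene body was extended by 1 kb on both sides in place of upstream alone. The share of control peaks with a 2KO peak (47.4%) was 43.2% when 50% of the peak had to be covered, 37.7% with 50% of both peaks, 49.4% with 5 kb allowed, 49.6% after merging within 3 kb and 56.8% with equal numbers of the widest peaks. The share of 2KO peaks with a control peak (76.6%) was 71.5, 58.5 and 60.5% under the first, second and last of these. With equal numbers the covered ratio was 0.758, the median log2 width ratio 0.012, and 597 genes were marked in the control list only, 419 in the 2KO list only, with 63.0% of control-marked genes kept. A 5 kb window gave 391 genes of the 2KO list only and 58.5% kept. The causes were not tested. Of 60 reruns of gene lists 58 stayed within their counting interval, and at a window of 0 the Hox share was 16.7% and that of the kinase inhibitors 0%. The Hox percentile stayed between 0 and 0.015 and that of the bHLH and neuronal factors between 99.8 and 99.99 over these reruns, while that of hair follicle genes went from 0.75 to 14.5, that of Merkel cell genes from 49.7 to 94.0 and that of the Pax, Lhx and Nkx list from 49.0 to 87.7. By bases, a unit chosen after the data were seen, 2 matchings were run. Drawing from all control peaks of the same width class put Hox at percentile 9.88, hair follicle genes at 6.89 and the other 3 transcription factor lists at 99.4 to 99.7. Drawing from the gene-end peaks nearest in width, adopted after those values were seen because peaks away from genes are kept less often, put them at 1.21, 0.91 and 76.6 to 86.6. By genes of nearest peak width, Hox lay at 0.21 and the bHLH and neuronal factors at 99.9. No matching could pair the widest Hox peaks with other peaks of their width. Height and depth are unknown, which limits all of these.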

Other observations

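Tests chosen only after the result was seen were those of transcription factor regions outside Hox, of the threshold at and away from gene ends, of receptor and channel genes, and of the X chromosome; the others were set down before the overlaps were computed, when the sizes and widths of the lists were known. Several of the widest control peaks without any 2KO peak lay outside the gene lists and, apart from Acot3, were named after their values were seen. They included a domain inside Zfhx3, a zinc finger homeobox gene with no peak at its ends in either list (chromosome 8, 108797331 to 108846449, 49.1 kb), and domains over the acyl-CoA thioesterase genes Acot3, Acot4 and Acot5 (chromosome 12, 84036970 to 84083563, 46.6 kb) and Tsc22d3, a glucocorticoid-induced gene (X chromosome, 140573771 to 140610730, 37.0 kb). Among hair follicle genes, the 12 control peaks kept 29.7% of their bases, beside 62.3% (35.1 to 83.5) in gene-end peaks of nearest width. The 8 Hox peaks kept 29.4%, beside 62.4% (33.1 to 86.5), and the 5 endothelial peaks 94.3%, beside 63.8% (24.3 to 93.8). For the widest Hox peaks there was no other peak of their width to draw. Counting by bases was also chosen after the data were seen. The 14 lists compared by bases were not corrected for their number, and with draws from all control peaks of the same width class hair follicle genes and Hox lay within the central range (22.6 to 77.6% and 18.7 to 81.3%) and the endothelial genes above it (11.9 to 87.6%).

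The first pattern is the 1910 control peaks with no 2KO peak. A stricter effective threshold in the 2KO list would remove weak regions first. With width taken as strength, it would keep over 90% of the widest of 5 equal width classes. The rise from 27.1% kept in the narrowest class goes that way, though a wide peak also meets an overlap of 1 bp more easily. The widest was kept at 67.8% (64.3 to 71.1), below the bound of 75% set against this explanation. Away from gene ends the widest class was kept at 40.4% (34.2 to 46.8). At gene ends it was 80.3% (76.6 to 83.6), between the bounds of 75 and 90% set for either outcome, so there a threshold stays open. Elsewhere the values argue against a threshold that removes peaks in order of width as the whole cause. Heights are not in the lists, so a threshold that removes wide regions of weak signal stays open at both positions. Retention that favours developmental transcription factor genes was tested on the 4 lists together, which lay at percentile 69.1 of matched draws, below the bound set beforehand. After that result the 3 lists other than Hox were pooled. Peaks that also mark Hox genes were left out of the base count. These included the peaks of Evx2 and Evx1, covered to 39.99 and 30.8%, so leaving them out raised the share. The remaining 139 control peaks kept 71.4% of bases, beside 63.4% (56.8 to 69.9) in gene-end peaks of nearest width (percentile 99.3). The percentile with the Evx peaks was not computed. By genes, with Evx1 and Evx2 counted, 117 of 146 control-marked ones were kept (80.1%). This was percentile 99.4 of draws from the same width classes and 97.9 of those nearest in width. The hypothesis that such regions outside Hox may keep more of the mark thus rests on leaving out Hox after the fact.

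The second pattern is the 548 2KO peaks with no control peak. Shifted or extended edges of control peaks would place at least 50% of them within 5 kb of one. Only 38 lay that near (6.93%, 5.09 to 9.37). The 548 were chosen for sharing no base with a control peak, so a peak that extends a control edge was left out beforehand. The share therefore cannot decide on edges, and shows only that most of these peaks lay over 5 kb from a control peak. Genes of neurotransmitter receptors and ion channels were picked as a set after reading the genes at these peaks and counting many families of symbols. Membership rests on the start of the symbol alone, so not every member need be neuronal. Of 105 marked ones, 14 (Gria1, Gria4, Gabrd, Gabrg1, Htr1a, Htr1f, Htr2c, Htr3b, Htr5a, Scn9a, Cacna1a, Kcnj6, Kcnv1 and Chrng) lay at such a peak, beside a median of 7 in random draws of marked genes, at percentile 99.1. A hypothesis that new marks may favour these genes was thus found and tested on the same lists, the choice among families is not corrected for, and 34 other genes of the set had a control peak with no 2KO counterpart.

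The third pattern is the X chromosome, where 24 of 84 control peaks had a 2KO peak (28.6%, 20.02 to 39.0), compared with 47.8% on the autosomes. Narrower X peaks would account for this if peaks of the same width elsewhere were kept as rarely, but these gave 44.5%, and 44.3% with position at genes matched too. Chromosome 15, at 32.7%, was also low, and of 20 chromosomes 4 had an interval wholly below and 5 one wholly above their expected share, so part of the spread may come from clustering of peaks along chromosomes. The sex of the pups could differ between the lists, and the loss of both proteins could act on the X chromosome; neither was tested.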
